A study of Macaca mulatta with 33 samples.

How the data were processed

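RNA of whole rhesus corpora lutea was hybridised to 33 Affymetrix Rhesus Genome arrays, 1 sample per array. The values used are the log2 intensities per probe set deposited by the authors; the background correction, summarization and normalization behind them are not given in the sources used here. Their range (2.6 to 15.12) and like array medians fit a log2 scale. No per-sample column was left unused. For arrays, their number (4 in most groups) limits the precision, and the p-values measure the spread between these samples, since the labels do not say whether each came from a separate animal.

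Of 52865 probe sets, 99 Affymetrix control probe sets were left out. A probe set was kept when it exceeded 6.18, the median of all values, in at least 4 arrays, which left 28911. Array medians differed by 0.183, more than the limit of 0.1 set beforehand, so each array was centred on its median. Probe sets were named through the annotation of the platform and the gene tables supplied with the data. Of those kept, 17606 have 1 symbol, 240 several and 11065 none, and 10507 genes have at least 1 kept probe set. Each gene is represented by its kept probe set with the highest mean over all arrays. Of the genes chosen to be reported in every comparison, CYP11A1, HSD3B1, LHCGR, HMGCS1 and VEGFA had no kept probe set with 1 symbol and are not reported. A further item is not reported here. Genome positions were not used.

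The groups are those of the labels (7 groups), and array set (1, 2 or 3) is the number in the array names. Group and array set were fixed terms of a single limma fit of all 33 arrays (limma 3.58.1 with statmod 1.5.0 in R 4.3.3, lmFit and eBayes with a mean-variance trend, 24 residual degrees of freedom, median residual SD 0.209). There were 11 two-sided comparisons: 3 of hCG, 2 of trilostane, 2 of R5020 against trilostane, 2 of R5020 against hCG alone, and 2 differences of effects between the days. Probe sets passed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, with no fold minimum. Levels, list scores and figures are adjusted for array set to the scale of set 1.

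The groups, comparisons, tests, gene lists, named-gene rule and first set of alternatives were fixed before the data were examined. For each comparison the rule names the 8 genes with the largest rise and the 8 with the largest fall among those that passed and whose groups do not overlap after removal of the array set effect, up to 3 passing members of each list with the smallest adjusted p, and STAR, CYP19A1, HSD3B2, PGR and FKBP5 always. Symbols beginning with LOC and probe sets with no symbol or several are skipped. Where a named gene passed with 1 group's mean under the median of all values, its fold is counted from that median and given as "at least". Other members of a list are quoted as examples of its count. Genes or probe sets outside the rule are said to be named after their values were seen.

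The 28 gene lists (656 entries, from general knowledge) cover steroidogenesis, cholesterol synthesis, cholesterol uptake, prostaglandins, hormone receptors, progestin and glucocorticoid response, angiogenesis, matrix, immediate early response, EGF family and ovulatory genes, apoptosis, inflammation, interferon response, MHC class II, cell cycle, hypoxia, endoplasmic reticulum stress, antioxidants, oxidative phosphorylation, and markers of endothelial cells, pericytes, fibroblasts, macrophages, lymphocytes, neutrophils and mast cells, red cells, granulosa cells and ovarian surface epithelium. They were tested with camera (preset correlation 0.01), adjusted over the lists of a comparison. Camera with an estimated correlation kept 3 of the 45 calls: MHC class II, matrix and apoptosis with R5020 at day 15. A list score is the mean over its members of the array's value minus the member's mean. Score differences were tested by exact two-sided permutation, 70 regroupings of 4 against 4, whose smallest p is 0.0286. The regroupings treat the array set effect estimated with the real groups as known, so these p-values leave out its error. They also treat the near-identical replicate 4 arrays of day 15 as separate samples.

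Day 15 hCG replicates 3 and 5 carry the same sample number. The rule set beforehand counted them as 1 sample only if each was the other's best match after the mean of each array set was subtracted. Replicate 5 matched replicate 3 best (r = 0.297 across probe sets), but replicate 3 matched another array better (r = 0.324), so they are 2 samples in the tests. The rule could hardly find a mutual match here. Set 3, which holds replicate 3, has 1 array of each day 15 group, and its trilostane and R5020 arrays are near-identical. If replicates 3 and 5 are 1 RNA, the p-values of comparisons with day 15 hCG may be too small. Because their values are near-identical, means and SD use the average of replicates 3 and 5 (n = 4), a departure from the rule made after the values were seen. Counting them as 1 sample was an alternative, with their correlation of 0.76 taken from their own differences, since a single pair gave no estimate otherwise. Replicate numbers were not used to pair the groups in the main fit. No comparison had all its number pairs correlated above 0.1 after removal of group and set effects. Of 4 number pairs, 3 did for 6 days of hCG against untreated tissue (r up to 0.42 across probe sets). For trilostane at day 15, 3 of 4 did. Pairing of some arrays by number is therefore not excluded. The numbers in the array titles differ from the replicate numbers in 4 day 15 arrays with trilostane or R5020. No comparison had all its pairs by title number above 0.1 either.

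The reversal by R5020 was measured as the covariance of the trilostane and R5020 changes with the trilostane arrays split 2 and 2 between them (6 splits), and compared with 50 simulations of independent probe sets without effects. After these values were seen, 1000 simulations were added in which each array is a random combination of the residual arrays. They keep the correlation between probe sets but not the likeness of near-identical arrays. Splits of the arrays were also drawn with day 15 hCG replicates 3 and 5 kept together. The methods were tested on simulated data with the real spread but with noise drawn independently for each probe set. The rates below therefore leave out the correlation between probe sets in the real arrays. Of changes of 2-fold, 84.2% were called for 1 day of hCG, 83.9% for trilostane at day 10, 66.6% for R5020 at day 10, 70.7% for trilostane at day 15 and 86.9% for R5020 at day 15, with 3.38% to 6.8% false calls. Of changes of 1.5-fold, 20.6% were called for R5020 at day 10. A shift of -0.5 put into the macrophage list was called in 10 of 10 runs, and a covariance of -0.0448 put in was found as -0.0423.

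The alternatives fixed in advance were no array set term, array set as a random block, only the array set that holds both groups, only the groups compared, no filter, a stricter filter (15361 probe sets), quantile normalization, no mean-variance trend, a 2-fold minimum, replicate number as a block, the pair counted as 1 sample, each array left out in turn, and for lists estimated correlation, fry and means over probe sets. Chosen after seeing the data were values without centring, leaving out the near-identical replicate 4 arrays, inferred animals as a random block, and for called lists leaving out arrays and using the shared array set. Centring each array was planned as an alternative but became the main choice. Where more than 100 splits of the arrays were possible, 100 were drawn at random; an earlier draw gave other counts but the same answers on chance. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.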

Results

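Whole corpora lutea of rhesus monkeys were profiled on 33 Affymetrix Rhesus Genome arrays. The corpus luteum secretes progesterone, and chorionic gonadotropin keeps it active in early pregnancy. Females received rising doses of human chorionic gonadotropin (hCG) to imitate that rescue, alone, with trilostane (TRL), or with trilostane and R5020. Trilostane inhibits 3-beta-hydroxysteroid dehydrogenase, the enzyme that makes progesterone, and R5020 is a synthetic progestin. Untreated tissue of luteal day 10 was the baseline, with 8 arrays. Tissue taken on day 10, after 1 day of hCG, gave 4 arrays with hCG alone, 4 with hCG and trilostane and 4 with R5020 added. Tissue taken on day 15, after 6 days of hCG, gave 5, 4 and 4 arrays.

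The array names place the samples in 3 array sets. Set 1 held 4 of the untreated arrays, all day 10 arrays with hCG alone or with trilostane, and 4 of the day 15 hCG arrays. Set 2 held the other 4 untreated arrays, all 4 day 10 arrays with R5020, and 3 day 15 arrays each with trilostane and with R5020. Set 3 held 1 array of each day 15 group. The array titles mark untreated replicates 1 to 4, all day 10 hCG arrays and day 15 hCG replicates 1 to 4 as reanalysis. No array with trilostane or R5020 bears that mark, and what it means is not stated. At day 10 it cannot be told apart from trilostane, and at day 15 only hCG replicate 5 lacks it among the hCG arrays. Between sets 2 and 1, 1910 of 28911 probe sets differed within groups at an adjusted p under 0.05 (limma), 1788 of them higher in set 2, so array set was a term in every comparison. Array medians before centring ran from 6.14 to 6.32 on the log2 scale. The first principal component held 20.6% of the variance.

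Among the 528 pairs of arrays, the median SD of the differences was 0.476 on the log2 scale, and 2 pairs stood far below it. Day 15 hCG replicates 3 and 5, which carry the same sample number, had an SD of 0.201 (r = 0.9932 across probe sets, which are not independent replicates). Replicate 4 of day 15 hCG with trilostane and replicate 4 of day 15 hCG with trilostane and R5020, which belong to different groups, had an SD of 0.192 (r = 0.9937 across probe sets). The next lowest pair was at 0.318.

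**Figure D1:**
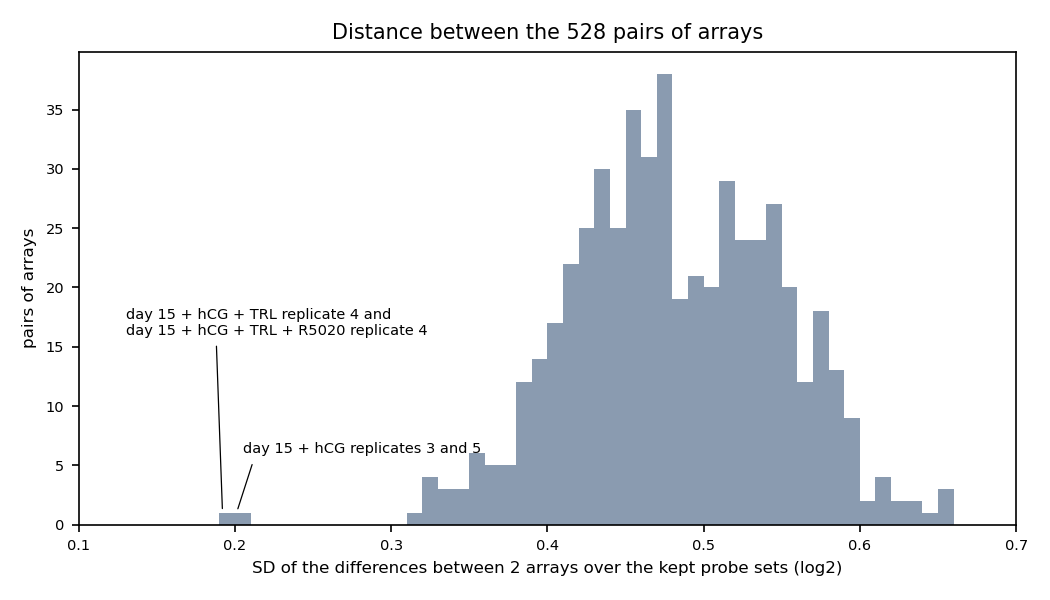
Number of array pairs (vertical axis) by the SD of their log2 differences over kept probe sets (horizontal axis) for all 528 pairs of arrays. The pairs at 0.192 and 0.201 lie apart from all others, which start at 0.318.

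Tissue after 1 day of hCG was compared with untreated day 10 tissue, to ask how luteal gene expression starts to respond. Genes of cholesterol synthesis rose together: of 16 measured members, 8 rose over all genes tested, 12 when adjusted over the list alone, and none fell. DHCR7, the enzyme of the final step to cholesterol, rose by 1.77 ± 0.33 (log2 change ± SE, adjusted p = 0.0018), and HSD17B7, which acts in cholesterol and estradiol synthesis, by 1.65 ± 0.25 (adjusted p = 0.00033). The list's median change was 0.78 (camera adjusted p = 1.1e-06, and adjusted p = 0.38 with an estimated correlation). Of 17 steroidogenesis genes, 15 lay above 0, 3 rose and none fell, with 6 higher when adjusted over the list alone (median 0.34, camera adjusted p = 0.014, and adjusted p = 0.37 with an estimated correlation). The risen steroidogenesis genes include POR, of which another probe set was called lower. CYP17A1, which makes androgen precursors, rose by 1.37 ± 0.39 (adjusted p = 0.04). STAR, which carries cholesterol into mitochondria, was already near the top of the scale, at 14.47 ± 0.07 (SD, n = 8) untreated and 14.64 ± 0.06 (n = 4) with hCG (adjusted p = 0.068).

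CYP11B1, a steroid 11-beta-hydroxylase outside the fixed lists, rose by 2.06 ± 0.60 (adjusted p = 0.043), a call that ended without any 1 of untreated replicates 1, 2, 3, 6 and 8 or of day 10 hCG replicates 1, 2 and 3 (adjusted p from 0.05 to 0.15). ELF5, an epithelial transcription factor, rose at least 6.89-fold, from a log2 level of 5.54 ± 0.50 (SD, n = 8) to 8.97 ± 1.39 (n = 4). TMPRSS7, a membrane serine protease, rose at least 7.03-fold (adjusted p = 0.0089), the lipid transporter MFSD2A 5.09-fold (adjusted p = 3.9e-05) and FST, the activin-binding protein follistatin, 4.29-fold (adjusted p = 5.3e-05). IRS2, a docking protein of insulin signalling on the list of progestin and glucocorticoid response genes, rose by 1.41 ± 0.29. The serotonin receptor HTR2B fell at least 8.25-fold, from 9.23 ± 0.57 (n = 8) to 6.10 ± 0.45 (n = 4). The calcium-binding protein S100A2 fell 5.13-fold, and BTC, a ligand of the EGF receptor, 2.38-fold. All 19 interferon response genes lay below 0 (median -0.43, camera adjusted p = 5.6e-06, and adjusted p = 0.38 with an estimated correlation), though no member passed alone. The apoptosis list was lower on balance (median -0.19, camera adjusted p = 0.034, and adjusted p = 0.37 with an estimated correlation), with 4 of 16 members above 0 and 2 higher and 3 lower when adjusted over the list alone.

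In all, 1369 probe sets passed after 1 day of hCG, 1018 higher and 351 lower. With quantile normalization 943 were higher and 566 lower. Leaving out day 10 hCG replicate 3 gave 611, and leaving out untreated replicate 4 gave 789. The CYP17A1 call ended without any 1 of untreated replicates 1, 3 and 4 or of day 10 hCG replicates 2, 3 and 4 (adjusted p from 0.063 to 0.15). The apoptosis call ended without untreated replicate 1 (adjusted p = 0.17) or day 10 hCG replicate 2 or 3 (0.13 and 0.10), and the steroidogenesis call ended with genes averaged over their probe sets (adjusted p = 0.14).

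Tissue after 6 days of hCG was compared with the same untreated baseline, to ask how the rescued corpus luteum differs from the mid-luteal one. This comparison differs in luteal day as well as in hCG. Cholesterol synthesis was again higher, with 8 of 16 genes risen over all genes, 10 when adjusted over the list alone, and none fallen (median 0.87, camera adjusted p = 1.4e-06, and adjusted p = 0.30 with an estimated correlation). EBP, a sterol isomerase, rose by 1.55 ± 0.26, and IDI1, which isomerises the isoprenoid building block, by 1.38 ± 0.23. Cell cycle genes fell: all 19 lay below 0, 6 fell over all genes and 17 when adjusted over the list alone (median -0.57, camera adjusted p = 2.8e-13, and adjusted p = 0.30 with an estimated correlation). AURKA, a mitotic kinase, fell by 0.50 ± 0.12 (adjusted p = 0.0093). Among steroidogenesis genes, CYP17A1 rose by 1.90 ± 0.36 (adjusted p = 0.0013) and STAR by 0.30 ± 0.05 (adjusted p = 0.00025), near the top of the scale, which leaves the size of its rise uncertain.

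After 6 days PGR, the progesterone receptor, had fallen at least 1.72-fold, from 6.97 ± 0.29 (SD, n = 8) to 5.93 ± 0.38 (n = 4). AREG, an EGF receptor ligand that luteinizing hormone induces at ovulation, fell 8.3-fold, from 13.35 ± 0.24 (SD, n = 8) to 10.19 ± 1.19 (n = 4), and BTC fell 2.47-fold. The prostaglandin D2 receptor PTGDR fell at least 3.59-fold and F2RL1, a protease-activated receptor, 4.51-fold. HTRA3, a serine protease, rose 5.94-fold, CEBPA, a transcription factor of metabolic and myeloid cells, 3.99-fold, and CP, the copper carrier ceruloplasmin, at least 1.77-fold. HSD3B2, the target of trilostane, was at 12.30 ± 0.41 (n = 4) against 13.28 ± 0.30 (n = 8), a change of -0.88 ± 0.26 (adjusted p = 0.043). That call ended without any 1 of untreated replicates 1, 2, 3, 4, 6 and 8 or of day 15 hCG replicates 1, 2 and 4 (adjusted p from 0.053 to 0.14). In all, 1636 probe sets passed, 1104 higher and 532 lower, and 903 and 767 with quantile normalization.

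Tissue after 6 days of hCG was also compared with tissue after 1 day, to ask which early changes persist. Of the 1018 probe sets higher after 1 day, 206 were also higher after 6 days and 493 were lower at 6 days than at 1 day. Of the 351 lower after 1 day, 79 were also lower after 6 days and 89 were higher at 6 days than at 1 day. The 206 and 79 come from comparisons that share the untreated arrays, which by itself favours the same sign, and the 493 and 89 from comparisons that share the day 10 hCG arrays, which favours opposite signs. The counts alone therefore show neither persistence nor return. ELF5 and TMPRSS7, among the strongest rises at 1 day, were lower at 6 days than at 1 day by at least 6.89-fold and 7.03-fold, and FST by 2.15-fold. INSM1, a zinc-finger transcription factor of endocrine cells, fell at least 7.97-fold, and AREG 7.79-fold. HSD3B2 fell by 1.38 ± 0.28 (adjusted p = 0.003), FDXR, which passes electrons to the mitochondrial steroid enzymes, by 0.70 ± 0.17, and HSD11B1, which regenerates cortisol, by 0.81 ± 0.16. FKBP5, a chaperone partner induced by progestins and glucocorticoids, fell by 1.5 ± 0.32 (adjusted p = 0.0039).

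Cell cycle genes were lower at 6 days than at 1 day, with 18 of 19 not above 0, 6 fallen and 9 fallen when adjusted over the list alone (median -0.42, camera adjusted p = 6e-05, and adjusted p = 0.79 with an estimated correlation). TPX2, a spindle assembly factor, fell by 0.95 ± 0.20. Macrophage and monocyte markers were higher, 14 of 15 above 0 (median 0.46, camera adjusted p = 0.026, and adjusted p = 0.79 with an estimated correlation). Inflammation genes were higher, 14 of 18 above 0, 2 risen and 3 risen when adjusted over the list alone (median 0.24, camera adjusted p = 0.041, and adjusted p = 0.59 with an estimated correlation). IL1RN, the interleukin 1 receptor antagonist, rose by 1.88 ± 0.36. Interferon response genes were higher, 14 of 19 above 0 and 1 risen (median 0.24, camera adjusted p = 0.026, and adjusted p = 0.79 with an estimated correlation), ISG20 by 1.19 ± 0.21. In all, 1941 probe sets passed, 802 higher and 1139 lower, 1172 without day 15 hCG replicate 2 and 1183 without day 10 hCG replicate 3. The macrophage, inflammation and interferon calls each ended without day 10 hCG replicate 2 (adjusted p = 0.13) or day 15 hCG replicate 3 (0.12 to 0.13). Without the array set term the macrophage median was 0.24 (adjusted p = 0.45), and the inflammation and interferon calls ended too (0.14 for both). Within the array set that holds both groups the adjusted p was 0.14 for macrophages, 0.12 for inflammation and 0.15 for interferon. The calls also ended without day 15 hCG replicate 1 for macrophages (0.059) and inflammation (0.071), day 10 hCG replicate 3 for inflammation (0.061) and interferon (0.15), and day 15 hCG replicate 2 for interferon (0.085).

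**Figure D2:**
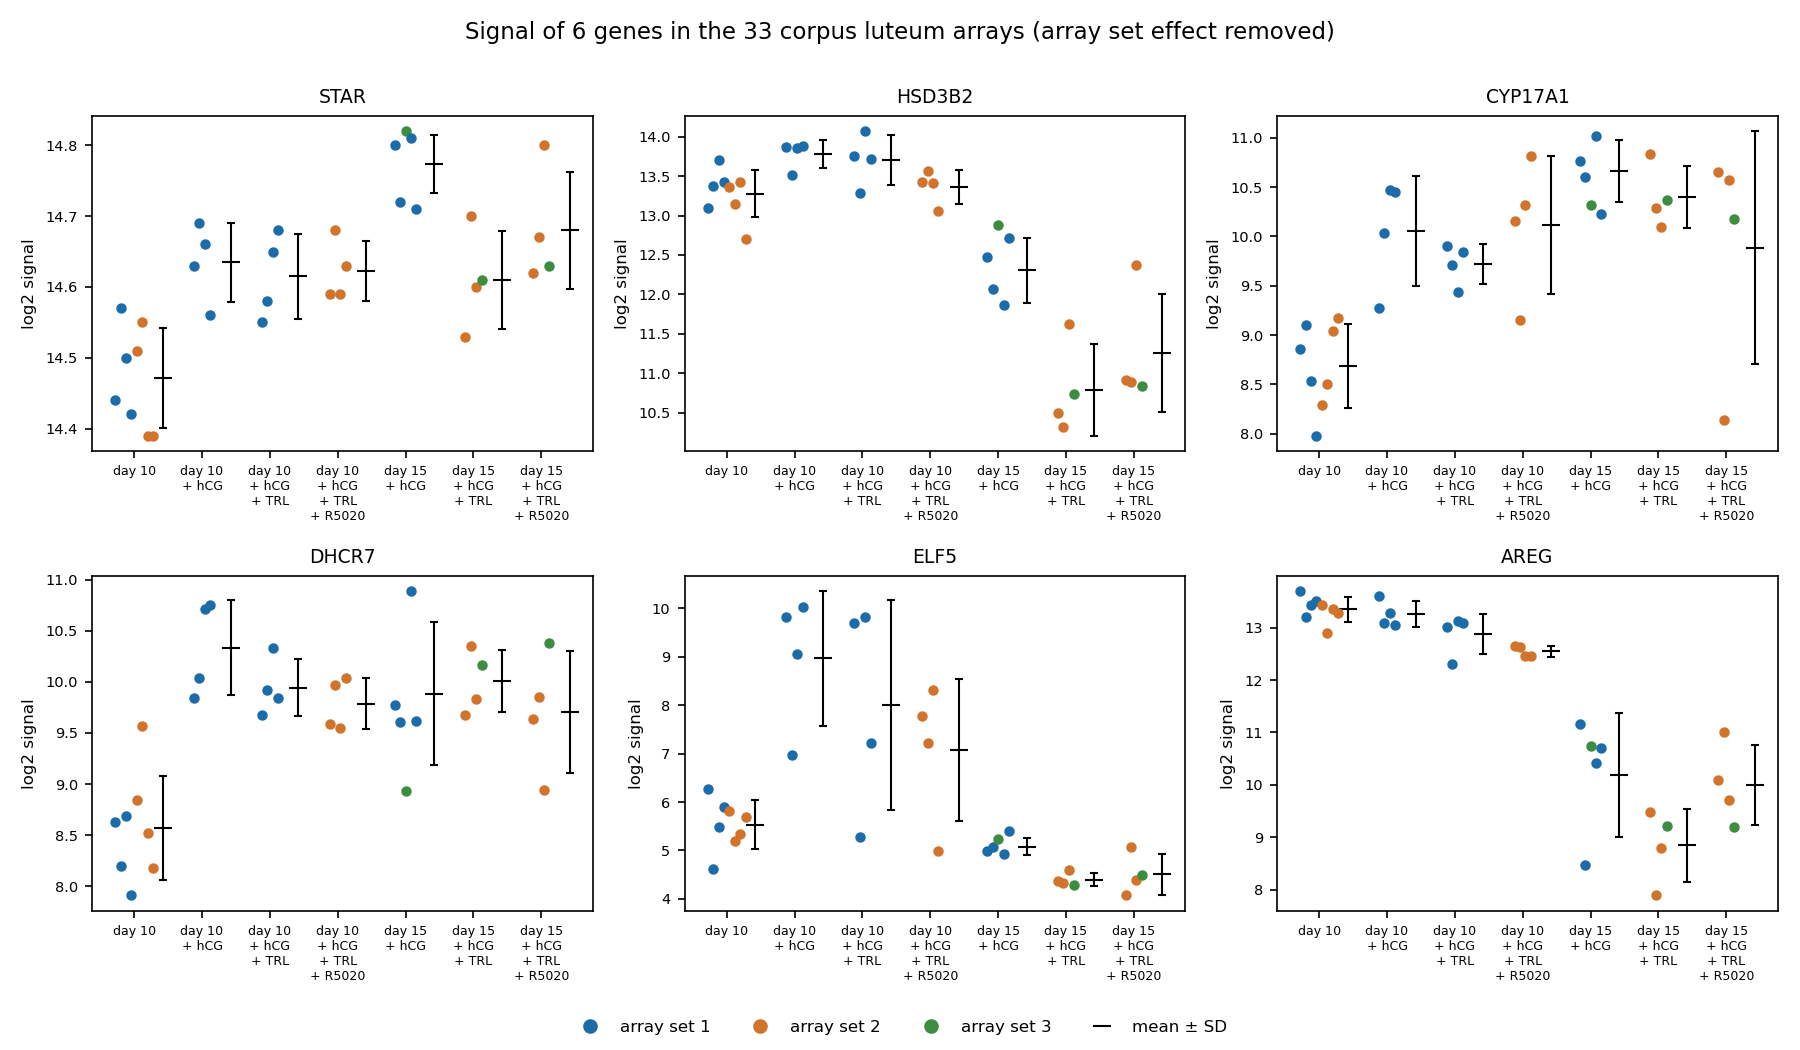
Log2 level (vertical axis) of 6 genes on each array by group (horizontal axis), adjusted for array set; points are arrays coloured by array set, black marks are means ± SD. ELF5 stands at 8.97 after 1 day of hCG against 5.54 untreated, AREG at 10.19 after 6 days against 13.35 untreated, and HSD3B2 at 10.79 after 6 days with trilostane against 12.30 with hCG alone.

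Trilostane with hCG for 1 day was compared with hCG alone, to ask what the block of steroid synthesis does at its start. Of 28911 probe sets, 1 fell and none rose (limma). It was TMEFF2, a membrane protein with follistatin-like domains, which fell at least 1.66-fold, from a log2 level of 6.92 ± 0.48 (SD, n = 4) to 5.16 ± 0.29 (n = 4). An unadjusted p under 0.05 (limma) was reached by 3606 probe sets, against 1446 expected by chance. Centring shifted this comparison as a whole: 37.1% of the kept probe sets lay above 0 (median change -0.06), against 48.6% (median -0.01) without centring. The excess of small p-values and the changes below include this shift. All 17 steroidogenesis genes lay below 0, with a median of -0.25, but the list did not pass (camera adjusted p = 0.23, fry adjusted p = 0.01). STAR, near the top of the scale, where a change can be missed, differed by -0.02 ± 0.05, HSD3B2 by -0.07 ± 0.29 and PGR by 0.76 ± 0.24, none past the threshold, though PGR passed without trilostane replicate 1 (1.01, adjusted p = 0.04). No list of 28 passed with camera, and 5 passed with fry. The TMEFF2 call ended without day 10 hCG replicate 4 (adjusted p = 0.12) or trilostane replicate 2 (0.096). The number of probe sets past the threshold was 0 without either of those arrays. It was 143 without trilostane replicate 1, 20 without trilostane replicate 3, and 43, 2 and 3 without day 10 hCG replicates 1, 2 and 3.

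R5020 added to hCG and trilostane for 1 day was compared with hCG and trilostane, to ask what progestin replacement does. No probe set passed (limma), and 892 had an unadjusted p under 0.05. The always named genes stayed within 1.04 ± 0.57 for CYP19A1, the aromatase, and -0.60 ± 0.32 for PGR. Among the lists, all 19 interferon response genes lay above 0 (median 0.45, camera adjusted p = 1.8e-06, and adjusted p = 0.22 with an estimated correlation). Immediate early response genes were lower, 2 of 15 above 0 (median -0.23, camera adjusted p = 0.00096, and adjusted p = 0.22 with an estimated correlation). Endoplasmic reticulum stress genes were lower, 3 of 15 above 0 (median -0.14, camera adjusted p = 0.0012, and adjusted p = 0.22 with an estimated correlation). Inflammation genes had 5 of 18 above 0 (median -0.30, camera adjusted p = 0.015, and adjusted p = 0.22 with an estimated correlation). The progestin and glucocorticoid response list was lower, not higher, with 6 of 23 above 0 (median -0.19, camera adjusted p = 0.044, and adjusted p = 0.38 with an estimated correlation). No member of these lists passed over all genes or over its list alone.

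The R5020 group of day 10 lies in another array set than the groups it is compared with. These sets are joined through the untreated arrays and, by way of set 3, through the day 15 arrays. Without the array set term the median was 0.14 for progestin response, 0.05 for endoplasmic reticulum stress, 0.01 for inflammation and 0.23 for interferon, none of them past the threshold, and 274 probe sets passed. The progestin call ended without trilostane replicate 1 or 2 or R5020 replicate 2 or 4 (adjusted p from 0.065 to 0.11), and the inflammation call without trilostane replicate 4 (0.17). The progestin call also ended without a filter (median -0.10, camera adjusted p = 0.20), without centring (0.063) and with genes averaged over their probe sets (0.062). Without the near-identical replicate 4 arrays of day 15 the inflammation median was -0.11 (camera adjusted p = 0.10). Against hCG alone, again across array sets, the day 10 R5020 tissue had no probe set past the threshold (limma), and 1683 at an unadjusted p under 0.05. There, 1 of 23 progestin and glucocorticoid response genes lay above 0 (median -0.35, camera adjusted p = 0.015, and adjusted p = 0.28 with an estimated correlation). Interferon genes had 16 of 19 above 0 (median 0.31, camera adjusted p = 4.6e-06, and adjusted p = 0.28 with an estimated correlation) and fibroblast markers 11 of 12 (median 0.30, camera adjusted p = 0.005, and adjusted p = 0.28 with an estimated correlation). The progestin call ended without day 10 hCG replicate 4 (0.066) and the fibroblast call without R5020 replicate 1 (0.22). Without the array set term the progestin median was 0 and the interferon median 0.04, neither past the threshold.

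Trilostane with hCG for 6 days was compared with hCG alone, to ask what a longer block of steroid synthesis does. Steroidogenesis genes were lower as a list, with 1 of 17 above 0 (median -0.16, camera adjusted p = 0.0057, and adjusted p = 0.17 with an estimated correlation). None passed over all genes, and 3 were lower when adjusted over the list alone. These were HSD3B2, at 10.79 ± 0.58 (SD, n = 4) with trilostane against 12.30 ± 0.41 (n = 4), a change of -1.61 ± 0.34 (adjusted p = 0.12), DHRS9, a retinol and steroid dehydrogenase, at -2.65 ± 0.77, and HSD11B1 at -0.82 ± 0.20. Immune lists were higher: 18 of 19 interferon genes (median 0.54, camera adjusted p = 2.2e-10, and adjusted p = 0.11 with an estimated correlation), 7 of 8 genes of MHC class II presentation (median 0.84, camera adjusted p = 5.9e-07, and adjusted p = 0.11 with an estimated correlation) and 14 of 15 macrophage markers (median 0.52, camera adjusted p = 3e-06, and adjusted p = 0.46 with an estimated correlation) lay above 0. Adjusted over the list alone, 4 MHC class II genes were higher, among them MAMU-DRA by 1.22 ± 0.34 and CD74, the invariant chain, by 0.88 ± 0.32, and 1 macrophage marker, the lysozyme gene LYZ, by 1.79 ± 0.43, while none passed over all genes.

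Over all genes, 7 probe sets fell and none rose with trilostane at 6 days. RBPMS, an RNA-binding protein of smooth muscle and other cells, fell by 0.83 ± 0.12 (adjusted p = 0.0036) and APPL2, an adaptor of endosomes, by 1.23 ± 0.23 (adjusted p = 0.048). The other 5 were a second probe set of each, HMGB3 (-1.41 ± 0.25), WDR41 (-0.79 ± 0.14) and KCNMB4, named after their values were seen. KCNMB4 has no size given, since its means of 4.99 and 5.92 both lay under the median of all values. The RBPMS change was -0.54 (adjusted p = 0.16) and the APPL2 change -0.99 (0.062) without the array set term, in groups that share only set 3. All 7 calls ended without day 15 hCG replicate 3 and without the near-identical pair of replicate 4 arrays, where RBPMS had an adjusted p of 0.31 and 0.11. The APPL2 call also ended without day 15 hCG replicate 1, 4 or 5 or trilostane replicate 1 or 3 (adjusted p from 0.075 to 0.15). The count was 23 without day 15 hCG replicate 2, 4 without its replicate 1 and 3 without replicate 4 or 5. It was 2, 4, 3 and 3 without trilostane replicates 1, 2, 3 and 4. HSD3B2 passed only without trilostane replicate 3 (-1.88, adjusted p = 0.048).

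Smaller shifts with trilostane at 6 days were seen in 4 lists with no member past the threshold. Oxidative phosphorylation had 1 of 18 above 0 (median -0.19, camera adjusted p = 0.0098, and adjusted p = 0.50 with an estimated correlation). Progestin and glucocorticoid response had 6 of 23 above 0 (median -0.16, camera adjusted p = 0.034, and adjusted p = 0.46 with an estimated correlation). Apoptosis had 9 of 16 above 0 (median 0.05, camera adjusted p = 0.039, and adjusted p = 0.30 with an estimated correlation). Cholesterol synthesis had 14 of 16 above 0 (median 0.11, camera adjusted p = 0.033, and adjusted p = 0.63 with an estimated correlation), and its median turned to -0.12 without day 15 hCG replicate 3 and to -0.09 without the near-identical pair. The cholesterol call also ended without day 15 hCG replicate 2 or trilostane replicate 2, 3 or 4 (adjusted p from 0.061 to 0.16), and the oxidative phosphorylation call without day 15 hCG replicate 3 (0.13). The progestin call ended without day 15 hCG replicate 1 or trilostane replicate 1 or 3 (0.054 to 0.25) and without the array set term (median -0.04, adjusted p = 0.30), in groups that share only set 3. The apoptosis call ended without day 15 hCG replicate 2 or 4 or trilostane replicate 1, where its median was -0.01, or 3 (0.06 to 0.19).

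R5020 added for 6 days was compared with hCG and trilostane, to ask what progestin replacement does over that time. No single probe set passed (limma), 1010 had an unadjusted p under 0.05, and 3 passed without trilostane replicate 4. Of the 28 lists, 11 passed with camera and 0 with fry. Immune lists were lower: all 8 MHC class II genes (median -0.69, camera adjusted p = 1.5e-08, and adjusted p = 0.035 with an estimated correlation), 17 of 19 interferon genes (median -0.42, camera adjusted p = 1.4e-09, and adjusted p = 0.058 with an estimated correlation) and 14 of 15 macrophage markers (median -0.51, camera adjusted p = 8.6e-08, and adjusted p = 0.19 with an estimated correlation) lay below 0. Adjusted over the list alone, 4 MHC class II genes were lower, among them MAMU-DPA (-1.20 ± 0.39). Matrix and protease genes were higher, 18 of 24 above 0 and 7 higher when adjusted over the list alone (median 0.21, camera adjusted p = 4.7e-05, and adjusted p = 0.035 with an estimated correlation). COL1A1, a chain of fibrillar collagen, changed by 1.35 ± 0.31, LOX, a collagen cross-linking enzyme, by 0.75 ± 0.23, and VCAN, versican, by 0.85 ± 0.29. None of these passed over all genes.

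The progestin and glucocorticoid response list was higher with R5020 at 6 days, 16 of 23 above 0 and 1 higher when adjusted over the list alone, ZBTB16, a progestin-induced transcription factor, by 1.12 ± 0.32 (median 0.21, camera adjusted p = 0.0029, and adjusted p = 0.12 with an estimated correlation). Apoptosis genes had 3 of 16 above 0 (median -0.08, camera adjusted p = 0.00028, and adjusted p = 0.035 with an estimated correlation). Markers of pericytes and smooth muscle had 8 of 9 above 0 (median 0.19, camera adjusted p = 0.0091, and adjusted p = 0.10 with an estimated correlation) and of fibroblasts 8 of 12 (median 0.14, camera adjusted p = 0.019, and adjusted p = 0.28 with an estimated correlation). Cholesterol synthesis had 1 of 16 above 0 (median -0.17, camera adjusted p = 0.0031, and adjusted p = 0.50 with an estimated correlation). Inflammation had 7 of 18 (median -0.06, camera adjusted p = 0.012, and adjusted p = 0.10 with an estimated correlation), and markers of T, NK and B cells had 4 of 11 (median -0.07, camera adjusted p = 0.012, and adjusted p = 0.058 with an estimated correlation). The progestin call ended without R5020 replicate 2 (0.087) and the pericyte call without R5020 replicate 3 (0.053). The cholesterol call ended without trilostane replicate 2 or 4 or R5020 replicate 3, where its median was -0.03 (0.056 to 0.20). The T, NK and B cell call ended without replicate 3 of either group (0.064 and 0.14). The inflammation call ended without trilostane replicate 1 or 3 or R5020 replicate 1, where its median was 0.07 (0.059 to 0.33). The fibroblast call ended without trilostane replicate 1 or 2 or R5020 replicate 2 or 3 (0.059 to 0.20).

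**Figure D3:**
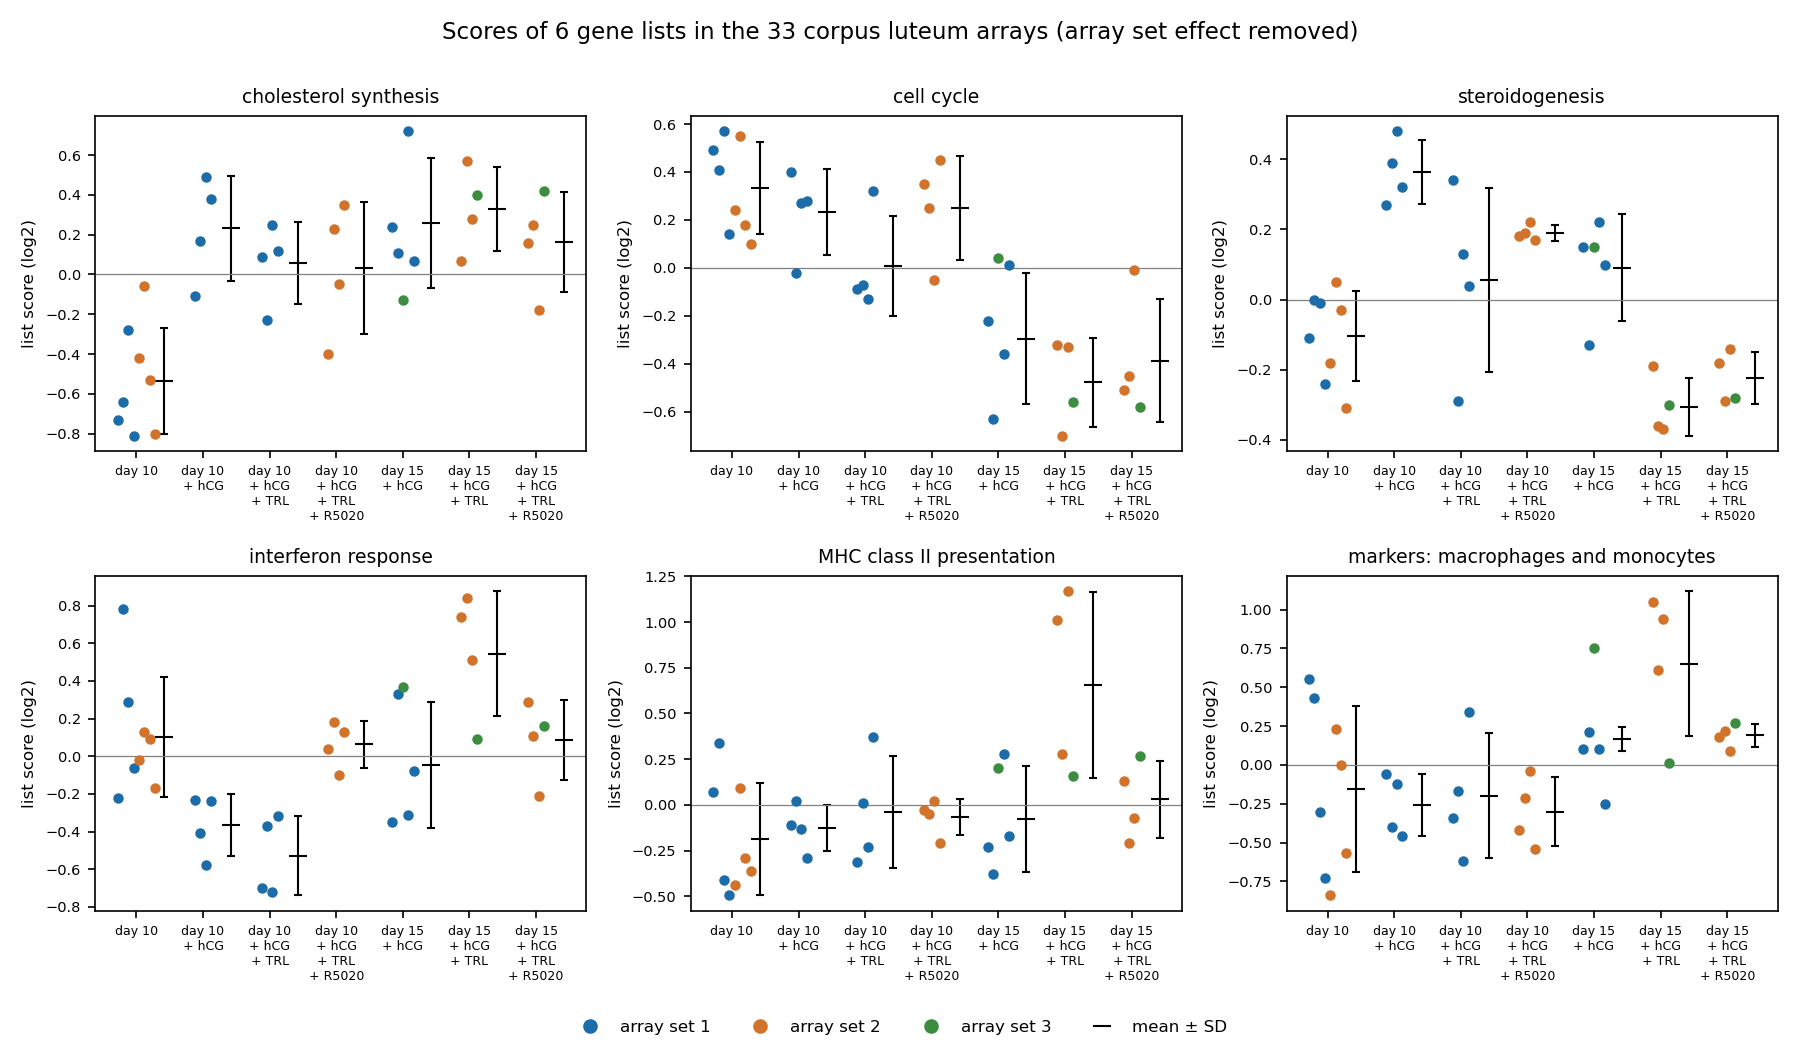
Score of 6 gene lists (vertical axis, mean log2 deviation of the members from their means over all arrays, adjusted for array set) on each array by group (horizontal axis); points are arrays coloured by array set, black marks are means ± SD. The macrophage score was 0.65 ± 0.47 (n = 4) after 6 days with trilostane, against 0.17 ± 0.07 with hCG alone and 0.19 ± 0.08 with R5020 added.

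Array by array, the immune scores of the trilostane group overlapped those of the other day 15 groups. The macrophage score was 0.65 ± 0.47 (SD, n = 4) with trilostane, 0.17 ± 0.07 (n = 4) with hCG alone and 0.19 ± 0.08 (n = 4) with R5020 added (exact two-sided permutation p = 0.143 for each difference, Benjamini-Hochberg 0.214 over 12 tests). The MHC class II score was 0.65 ± 0.51 with trilostane, -0.08 ± 0.29 with hCG alone (exact p = 0.0857) and 0.03 ± 0.21 with R5020 (exact p = 0.0571). The pericyte score was -0.27 ± 0.13 with trilostane against 0.02 ± 0.14 with hCG alone (exact p = 0.0286, adjusted 0.206). Against hCG alone, the day 15 R5020 tissue had no probe set past the threshold (limma), 1142 at an unadjusted p under 0.05, and no list past it. HSD3B2 stood at 11.25 ± 0.75 (n = 4) with R5020, a change of -1.15 ± 0.34 from hCG alone.

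How far R5020 moved the trilostane changes back was measured by the covariance of both log2 changes over 28911 probe sets, with the shared trilostane arrays split between the comparisons. A negative value means opposite changes. At 6 days it was -0.0109 ± 0.00442 (SD over 6 splits), within the spread of simulated arrays drawn independently. Of 1000 simulations without any effect, which keep the correlation between probe sets, 171 were as low (95% of the 1000 from -0.0321 to 0.0269). They do not hold the near-identical replicate 4 arrays of the trilostane and R5020 groups, whose shared noise favours a positive value. The simulations therefore do not decide whether R5020 moved the changes back. The value at 6 days lay below 50 simulations of independent probe sets (0.000612 to 0.00475), a range too narrow for correlated ones. It was -0.0356 without trilostane replicate 4, -0.0197 without day 15 hCG replicate 3, -0.0165 and -0.00625 without R5020 replicates 1 and 2, and -0.00299 and -0.000239 without trilostane replicates 2 and 1. No simulations were made with arrays left out. The value at 6 days was 0.000476 without the array set term, no longer negative. At 1 day it was 0.00373 ± 0.0122 (464 of 1000 simulations as high).

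Whether these responses differed between the days was tested directly as a difference of effects. No probe set passed for trilostane (limma, 1098 at an unadjusted p under 0.05) or for R5020 (824). HSD3B2 differed by -1.54 ± 0.45 for trilostane, day 15 minus day 10, and by 0.80 ± 0.49 for R5020 (adjusted p = 1 for both). Among lists, all 19 interferon genes had a higher trilostane effect at day 15 (median 0.73, camera adjusted p = 1e-06, and adjusted p = 0.47 with an estimated correlation), as did 7 of 8 MHC class II genes (median 0.72, camera adjusted p = 0.016, and adjusted p = 0.56 with an estimated correlation). Immediate early genes had a lower one, 3 of 15 above 0 (median -0.21, camera adjusted p = 0.0056, and adjusted p = 0.47 with an estimated correlation). The MHC class II call ended without trilostane replicate 1 of day 10 or 1 or 3 of day 15, or day 15 hCG replicate 2 (0.054 to 0.22), and the immediate early call without day 15 hCG replicate 1 (0.077). Without the array set term the interferon median was 0.42 and the MHC class II median 0.46, neither past the threshold.

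For R5020, 18 of 19 interferon genes had a lower effect at day 15 than at day 10 and 7 were lower when adjusted over the list alone (median -0.91, camera adjusted p = 3.7e-15, and adjusted p = 0.051 with an estimated correlation). MHC class II genes had 1 of 8 above 0 (median -0.65, camera adjusted p = 0.0029, and adjusted p = 0.39 with an estimated correlation). Immediate early genes had 13 of 15 above 0 (median 0.50, camera adjusted p = 0.00012, and adjusted p = 0.15 with an estimated correlation). Progestin and glucocorticoid response genes had 17 of 23 (median 0.27, camera adjusted p = 0.00016, and adjusted p = 0.14 with an estimated correlation), and EGF family and ovulatory genes 9 of 14 (median 0.20, camera adjusted p = 0.045, and adjusted p = 0.21 with an estimated correlation). Without the array set term the progestin median turned to -0.04 and its call ended, as did the MHC class II and EGF calls. The MHC class II call ended without day 15 trilostane replicate 3 (0.075). The EGF call ended without day 10 trilostane replicate 3 or 4, day 10 R5020 replicate 1 or 4, day 15 trilostane replicate 2 or 4, or day 15 R5020 replicate 1 (0.059 to 0.17).

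Of the 28 lists, 17 passed with camera in at least 1 comparison and 11 in none. The lowest camera adjusted p of each of the 11 was 0.055 for red cell markers (day 10 R5020 against hCG, median 0.72), 0.059 for cholesterol uptake, storage and efflux (6 days of hCG, median 0.31), 0.069 for hormone receptors (6 days against 1, median 0.16) and 0.11 for the hypoxia response (6 days of hCG, median -0.01). It was 0.11 for endothelial markers (6 days of hCG, median -0.10), 0.16 for granulosa markers (day 10 R5020 against hCG, median 0.27), 0.21 for antioxidant and glutathione genes (R5020 by day, median -0.18) and 0.22 for angiogenesis (1 day of hCG, median -0.07). It was 0.32 for the prostaglandin pathway (6 days of hCG, median 0.03 but mean -0.43, with a lower test direction), 0.39 for ovarian surface epithelium (day 15 R5020, median 0.10) and 0.65 for neutrophil and mast cell markers (6 days of hCG, median 0.22).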

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

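The tests of the immune lists below were chosen only after the results were seen, and the demand for an exact p under 0.05 on the macrophage score was added after its values were known; the tests of day differences were planned. After 6 days, lists of interferon response, MHC class II and macrophage genes were higher with trilostane and lower with R5020 added, by camera. With an estimated correlation only the MHC class II call with R5020 held (adjusted p = 0.035), while interferon, MHC class II and macrophages had 0.11, 0.11 and 0.46 with trilostane, and interferon and macrophages 0.058 and 0.19 with R5020. With fry 0 lists passed for R5020 at 6 days, so that MHC class II call did not hold there. The effects on interferon response and MHC class II differed from those at 1 day. By day (day 15 minus day 10) the trilostane effect differed by a median of 0.73 for interferon response and 0.72 for MHC class II, and the R5020 effect by -0.91 and -0.65. None of these differences held with an estimated correlation (adjusted p = 0.47, 0.56, 0.051 and 0.39).

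An array set difference that acts alike on both groups cancels in the R5020 part, since each group has 3 arrays in set 2 and 1 in set 3. Within set 2 alone, 3 arrays against 3, the medians were -0.83 for macrophage markers, -0.94 for MHC class II and -0.63 for interferon. With all arrays they were -0.51, -0.69 and -0.42, but set 2 alone also leaves out the near-identical replicate 4 arrays. For the trilostane part the design keeps an array set difference open. Its groups share only set 3, with 1 array each, where the score was higher with trilostane in 0 of 3 lists. That trilostane array is the one near-identical to an R5020 array, so it decides nothing about trilostane. A change in the share of luteal cells could raise all other cell types alike, but the macrophage score minus the mean of the endothelial, pericyte and fibroblast scores differed by -0.67 between R5020 and trilostane (exact two-sided p = 0.0857, smallest possible 0.0286), which leaves it undecided. Trilostane against hCG alone raised none of those other scores clearly: they differed by 0 for endothelial, -0.28 for pericyte and -0.15 for fibroblast markers. Only the pericyte difference had an exact p under 0.05 (0.0286, adjusted 0.206), so a change in the share of luteal cells stays undecided. More macrophages with trilostane and fewer with R5020 may be a candidate explanation: 13 of 15 markers were both higher with trilostane and lower with R5020, but both comparisons share the trilostane arrays and the score had an exact p of 0.143 in each. The most abundant marker, the complement gene C1QA, was at a log2 level of 12.38 ± 0.63 (SD, n = 4) with trilostane, 11.77 ± 0.28 with hCG alone and 11.77 ± 0.34 with R5020, and 0 of the 15 markers are in another list. A biological effect of steroid withdrawal on immune genes was not separated from these.

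Other lists also had effects that differed between the days by the same planned test. The trilostane effect on the immediate early response differed by a median of -0.21. The R5020 effect differed by 0.27 for progestin and glucocorticoid response, by 0.50 for the immediate early response and by 0.20 for EGF family and ovulatory genes. None of these held with an estimated correlation, as the report gives.

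Single arrays lay far from the rest of their group in 10 of 175 groups of values tested, where chance alone gives about 1 in 20, or 9. HSD3B2 was at a log2 level of 13.51 in day 10 hCG replicate 2, against 13.86 in the nearest, and at 12.37 in day 15 R5020 replicate 3, against 10.91. CYP19A1 was at 12.63 in day 15 hCG replicate 2, against 13.60. FKBP5 was at 7.60 in day 10 trilostane replicate 2 (nearest 8.32), at 9.08 in day 10 R5020 replicate 3 (nearest 7.86) and at 7.76 in day 15 hCG replicate 1 (nearest 6.99). The cell cycle score was 0.32 in day 10 trilostane replicate 4 (nearest -0.07). The progestin and glucocorticoid score was 0.05 in day 10 R5020 replicate 3 (nearest -0.06). The oxidative phosphorylation score was 0.14 in day 15 R5020 replicate 2 (nearest -0.06). The median of day 10 trilostane replicate 2 was 6.32 before centring (nearest 6.23).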

How the results depend on the processing

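The alternatives chosen only after seeing the data were no centring, leaving out the near-identical replicate 4 arrays, inferred animals as a block, and for called lists leaving out arrays and the shared array set. Counts of probe sets not named here stayed within 1.5 times. With only the array set that holds both groups, fewer arrays gave 672 for 1 day of hCG, 1069 for 6 days and 0 for trilostane at day 10. With only the groups compared, the counts were 750, 829 and 707 (6 days against 1), 0 for trilostane at day 10 and at day 15, 820 for R5020 at day 10, where no set term could be estimated, and 3 for R5020 by day. Without the set term R5020 at day 10 gave 274. Without a filter trilostane gave 2 at day 10 and 12 at day 15, and R5020 at day 15 gave 2. The stricter filter gave 0 and 11 for trilostane. A 2-fold minimum, which only removes calls, gave 342, 383, 475 and, for trilostane at day 15, 3. Replicate number as a block gave 0 for trilostane at both days. With the day 15 hCG pair as 1 sample, trilostane at day 15 gave 3, and without the near-identical arrays 0. Leaving out 1 array gave 611 to 1645 for 1 day of hCG, 1099 to 1847 for 6 days, 1172 to 2064 for 6 days against 1, 0 to 143 and 0 to 23 for trilostane at day 10 and 15, 0 to 3 for R5020 at day 15, and 0 for the others (limma; unadjusted counts are in the report).

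Of 45 list calls, 3 held with an estimated correlation and 42 kept their direction without passing; fry made 18 calls, 7 of them shared. Without the set term 30 of the 45 passed, without centring 42, without the near-identical arrays 38, and 22 were lost without some array. Of 132 named-gene calls, 52 were lost without some array and 38 under another alternative. Averaged over its probe sets, POR after 1 day of hCG turned from 0.63 to -0.14 (adjusted p = 0.46), as another of its probe sets was called lower. The reversal covariance at day 10 was -0.0154 without the set term, and from -0.00688 to 0.00917 without 1 array. At day 15 it turned to 0.000476 without the set term, and was -0.00591 without a filter, -0.034 without the near-identical arrays and from -0.0356 to -0.000239 without 1 array. Except where stated, the cause was not tested. Signal over background limits dim genes: probe sets that never reach the median of all values were not tested.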

Other observations

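The tests of near-identical and marker-sharing arrays and the splits of the samples were chosen only after the results were seen; the tests of the array sets were written beforehand.

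Single genes beyond the pathways of the report also changed with hCG. MGST1, a membrane glutathione transferase, rose by 1.23 ± 0.17 after 6 days (adjusted p = 5.1e-05), and GSTA3, a glutathione transferase that can also isomerise steroids, by 0.60 ± 0.10 after 1 day (adjusted p = 0.00067). The antioxidant and glutathione list passed in no comparison. CYBRD1, a ferric reductase, rose by 1.96 ± 0.23 from 1 to 6 days (adjusted p = 4.5e-06). PGRMC2, a membrane-associated partner of progesterone signalling, rose by 0.44 ± 0.10 after 6 days, where PGR fell.

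Markers of other cell types fell singly after 6 days of hCG. KCNJ8, a potassium channel of pericytes, fell by 0.76 ± 0.14 (adjusted p = 0.0015), THY1, a fibroblast surface protein, by 0.59 ± 0.15 (adjusted p = 0.012) and KRT8, a keratin of epithelial cells, by 1.06 ± 0.23 (adjusted p = 0.0056). None of their lists passed in that comparison.

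Without the array set term, 274 probe sets passed for R5020 at day 10, 264 of them higher. A difference between array sets 1 and 2 may account for most of them. In untreated arrays, which entered those calls only through the shared estimate of the spread, 99.3% of them differed the same way between the sets. The median of that difference was 0.31, against a median called change of 0.60. After that difference was taken off, a median change of 0.27 was left, too little to tell whether R5020 adds to it. In the 3 prime to 5 prime signal of actin and GAPDH, the compared groups were apart in 0 of these transcripts. Ranges of so few arrays overlap easily, so RNA degradation is left open. For actin, untreated replicates 6 and 9 of set 2 were at 1.43 and 1.55 (log2 3 prime minus 5 prime). Replicates 7 and 8 of set 2 were at 0.671 and 0.826, and the untreated arrays of set 1 at most at 1.06.

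Replicate 4 of day 15 trilostane and replicate 4 of day 15 R5020 differed by an SD of only 0.192, like the 0.201 of the 2 arrays that carry the same sample number, so the same RNA on both arrays is a candidate explanation. A shared array set does not bring arrays that close (0.418 at the least to the remaining set 3 array). Separate corpora lutea of one animal stay open: other pairs that agree on every marker were at 0.325 at the least, but the pair with the same sample number, whose origin is not settled, also agrees on every marker. More widely, 15 pairs of arrays, 14 of them from different groups, agreed on all 13 probe sets with 2 separate levels, against at most 4 pairs in 1000 shuffles, and 13 such pairs tested on the other probe sets had a mean residual correlation of 0.29 (0.01 to 0.63) against -0.01 for other pairs (permutation p = 0.001, the smallest possible). The shuffles moved each marker on its own, which removes any correlation between markers and can lower the number of agreeing pairs. The permutation treated the pairs as independent, although several share an array. Some animals may have given corpora lutea to several groups, a hypothesis found and tested on the same data. With 21 inferred animals as a random block, 1657, 2423 and 2392 probe sets passed in the 3 hCG comparisons.

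Other splits of the same arrays showed how often regrouping alone gives as many calls. In each hCG comparison 1 of 100 splits drawn gave as many, the real one. The real count and the highest other count drawn were 1369 and 1273 probe sets for 1 day and 1636 and 366 for 6 days. For 6 days against 1 they were 1941 and 1320. Chance is thus unlikely for these counts but not excluded. More splits were possible than were drawn, and arrays that share an animal would not be exchangeable. The split with 1273 swapped only untreated replicate 7 with day 10 hCG replicate 2, and the split with 1320 is the real one with its groups exchanged, but for day 15 hCG replicate 3. With the near-identical day 15 hCG replicates 3 and 5 kept on one side, the real split again gave the most, 1 of 100 for 6 days and 1 of 56 for 6 days against 1, with 1287 in the highest other of each. For trilostane at day 15 chance is not excluded. Of 100 splits, 3 gave 7 or more, but 4 of 56 did with that pair kept together, and the highest other was 29 in both. Those splits mix array sets that the real groups mostly keep apart, so their contrasts can be more precise than the real one. Chance cannot be excluded for trilostane at day 10 either (1 probe set, 152 in the highest other, 9 of 35 splits as large). In both, splits that call several times the real count may reflect a structure among the samples. At day 10, hCG replicate 3 and trilostane replicate 1 agreed on all 13 markers. Without that trilostane array 143 probe sets passed, but without that hCG array only 3 did. For counts of 0, which every split reaches, the splits decide nothing. These are R5020 at day 10 (35 of 35, highest other 45), R5020 against hCG at day 10 (35 of 35, 173), R5020 at day 15 (35 of 35, 18), R5020 against hCG at day 15 (100 of 100, 15), trilostane by day (100 of 100, 28) and R5020 by day (100 of 100, 4).

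For the number of lists that pass, chance cannot be excluded in any comparison, and where it is 0 the splits decide nothing. Where the compared groups lie in different array sets, as for R5020 at day 10 and mostly for trilostane at day 15, the splits mix the sets. Their contrasts can then be more precise than the real one, so the numbers are not fully comparable. The real and highest other numbers were 4 and 11 for 1 day of hCG (31 of 100 splits as large), 2 and 9 for 6 days (84), 4 and 8 for 6 days against 1 (34), 0 and 9 for trilostane at day 10 (35 of 35) and 5 and 10 for R5020 at day 10 (10 of 35). They were 3 and 5 for R5020 against hCG at day 10 (13 of 35), 8 and 11 for trilostane at day 15 (17 of 100), 11 and 11 for R5020 at day 15 (2 of 35), 0 and 8 for R5020 against hCG at day 15 (100), 3 and 11 for trilostane by day (59) and 5 and 12 for R5020 by day (40).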
